A study of Mus musculus with 4 samples.

How the data were processed

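RNA of sorted ICOS-positive ILC2 was amplified and labelled with biotin for Affymetrix arrays, per the labels' protocols. The design has 2 littermate control and 2 Ets1-deleted samples with 1 array each. The deposited values are probe set intensities that the authors made with RMA (background correction, quantile normalization and summary over probes), per the submitters' processing notes. The software, its version and any further scaling are not given in the sources used here. The deposited intensity values run from 39.5 to 23291, so they were read as linear and turned into log2. The scale is an inference from the values, since RMA commonly gives log2. The array medians (96.5 to 97.7) and quartiles lie close together, as after quantile normalization, so no further normalization was applied. Summaries of this kind level off near 40 to 100 intensity units, which understates the fold of genes that are dim in one group.

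Genes were named through the platform annotation. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed and stay unnamed here; 64 are the array maker's controls. The gene IDs of 34754 matched the RefSeq gene table, and 0 symbols needed an update. Each of 18194 genes was represented by its probe set with the highest mean over the 4 arrays. A gene was tested where that mean reached the median of the means of all probe sets (50th percentile, 97.44 intensity units), which left 10873. Of 1451 called genes with more than 1 probe set over that limit, 173 had probe sets that differed in sign. Genes without a probe set of 1 symbol were not analysed here.

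The fit was lmFit and eBayes of limma (version 3.58.1 in R 4.3.3), Ets1-deleted minus control, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. It has 2 residual degrees of freedom per gene and 9.75 prior degrees of freedom. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 25 lists, then again with the correlation estimated from the residuals. Of the 25 lists, 11 passed with the preset value and 0 with the estimated one, where 1 list (glycolysis and hypoxia) had an unadjusted p under 0.05. The directional test of fry, which does not compare a list with other genes, passed 14. Nothing says that the arrays come from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Their number limits the precision.

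The groups, the test, the lists, the alternatives and the rule for naming genes were set before the data were examined. Named were Ets1, the 12 largest rises and 12 largest falls among called genes without overlap (predicted genes and clones passed over), and from each list the 4 members of smallest p. List members past the threshold could be named too, and Il1rl1, Gata3, Rora, Il5, Il13, Icos and Klrg1 whatever their result. The fit was tested on simulated data for the 10873 genes of this comparison with 200 changed. It recovered 80.6% of genes changed by a log2 difference of 0.5 and 100% of those changed by 1 or 2. There were 11 false calls among 198, and 0 calls where no gene was changed. The simulated noise was normal and independent between genes, with variances already shared across genes. The 200 changed genes are far fewer than the 2900 called here. These figures check the code and do not give the error rates in the real data.

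The alternatives were a repeated quantile normalization, median centring, no filter and a stricter one (70th percentile) on dim genes, the mean over a gene's probe sets, and 1 row per probe set. Others were a replicate block, a variance trend, robust and ordinary variances, a threshold of 0.1, a limit of 1.5-fold, fry, the estimated correlation and leaving out each array. A subtraction of each array's 5th percentile with a floor of 16 intensity units was added after seeing the data.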

Results

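Transcript levels were measured on Affymetrix arrays in group 2 innate lymphoid cells (ILC2) of C57BL/6 mice. ILC2 are tissue lymphocytes without rearranged antigen receptors that make type 2 cytokines. The cells had grown for 2 weeks on OP9-DL1, a bone marrow stromal line that displays a Notch ligand, with IL-7 and IL-33, and ICOS-positive cells were sorted for RNA. There were 4 arrays, 2 from littermate controls and 2 from mice with a deletion of Ets1, which encodes a transcription factor of the ETS family. The 45101 probe sets gave 10873 genes bright enough to test, with array medians between 96.5 and 97.7 intensity units. The number of arrays limits the precision, and n = 2 per group throughout. The 1 comparison, Ets1-deleted minus control, addresses which genes differ between the genotypes in these cultured and sorted cells. Differences are on the log2 scale, ± SE from limma.

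Ets1 itself was far lower in the Ets1-deleted arrays with each of its 4 probe sets, by 8.69-, 6.88-, 7.93- and 11.4-fold. On its brightest probe set the controls read 1272 and 1231 intensity units and the Ets1-deleted arrays 138.1 and 180.2, a log2 difference of -2.99 ± 0.13 (limma, adjusted p = 2.17e-08). Where the probe sets lie relative to the deleted part of the gene is not given in the sources used here. The ILC2 transcription factor gene Gata3 differed by 0.08 ± 0.11 (adjusted p = 0.658 with limma), while Rora, another regulator that ILC2 need, rose by 1.29 ± 0.12. Il5 rose by 0.83 ± 0.16 and Il13 by 0.69 ± 0.13, the main type 2 cytokine genes of these cells. Klrg1, a surface receptor of mature ILC2, fell by 1.60 ± 0.11. Icos, whose protein was the sorting marker, was lower by a log2 difference of -0.38 ± 0.11 (limma, adjusted p = 0.0232). The Icos call was lost without control 1 (-0.35), control 2 (-0.42) or Ets1-deleted 1 (-0.33), with adjusted p of 0.14, 0.0653 and 0.0969 in limma, where the lone array of a group is assumed to vary like the other group. It was also lost with the array floor subtracted (-0.39, adjusted p = 0.076 in limma). Il1rl1, the IL-33 receptor gene, was not analysed here.

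**Figure D1:**
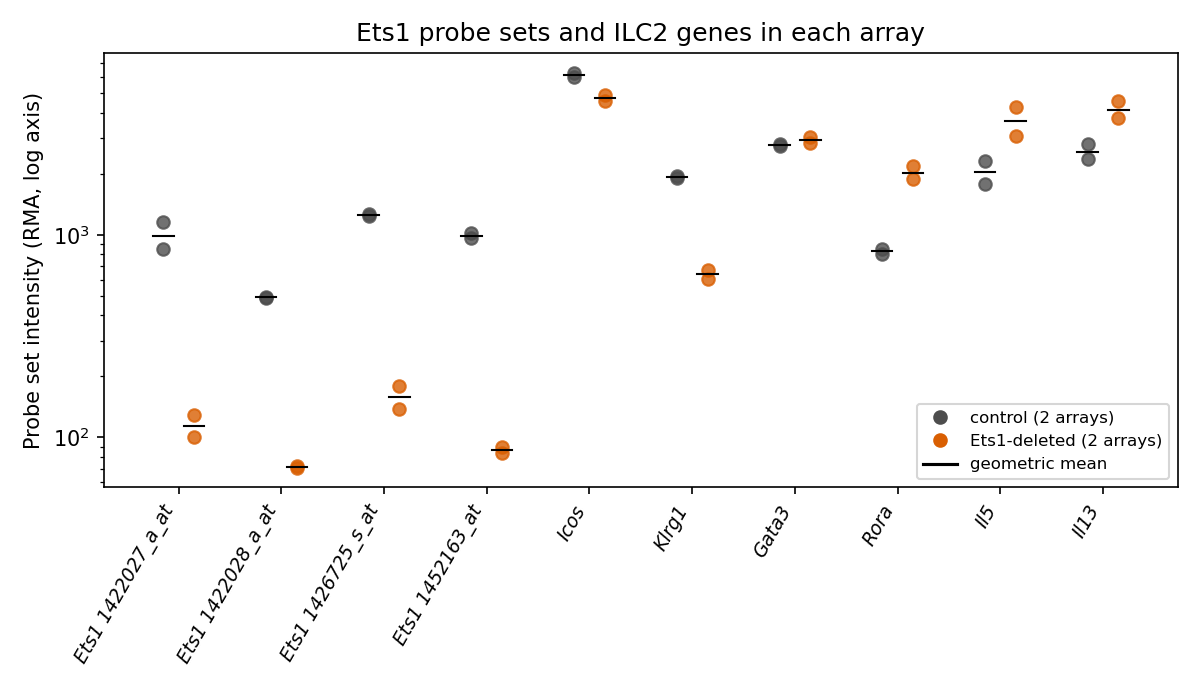
Probe set intensity (RMA values, log axis) of the 4 Ets1 probe sets and 6 ILC2 genes in each array, with control arrays in grey, Ets1-deleted arrays in orange and bars at geometric means. The Ets1-deleted arrays lie far below the controls for Ets1 and Klrg1 and above them for Rora, Il5 and Il13, and the Gata3 points lie close together.

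The steepest rises were in Cpa3, a mast cell carboxypeptidase gene (4.07 ± 0.12, 16.8-fold), and Il24, a cytokine gene of the IL-10 family (4.05 ± 0.12, 16.6-fold). Cpa3 went from 85.9 and 78.3 intensity units in the controls to 1497 and 1261. Fam25c rose by 3.96, the AP-1 family gene Jdp2 by 3.47, and Plin2, which coats lipid droplets, by 3.28. Cd3e and Cd247, which encode parts of the T cell receptor complex, rose by 3.28 and 3.11, although 1 of the 4 bright Cd247 probe sets went the other way (-0.21). Plxdc2 rose by 3.26, the receptor gene Cd160 by 3.06, Plac8 by 3.03, the zinc finger gene Zbtb32 by 3.03, and Ptgs2, which encodes cyclooxygenase 2, by 2.80. After Ets1, the largest falls were in Smpdl3a, a phosphodiesterase gene (-2.59 ± 0.12), and the sulfotransferase gene Chst2 (-2.59 ± 0.11), whose second bright probe set differed by -0.06. Falls followed in the actinin gene Actn2 (-2.37), the interferon-inducible Ifi209 (-2.35), the pseudokinase gene Trib2 (-2.27) and the protease gene Klk8 (-2.27). Gpr18 (-2.21), the calcium channel gene Ryr1 (-2.19), the casein gene Csn2 (-2.19), Enc1 (-2.17) and Cd79b, known from the B cell receptor (-2.12), fell as well. The bright probe sets that moved least gave 0.85 for Jdp2, 1.28 for Plxdc2, 1.08 for Cd160 and -0.44 for Enc1. Adjusted p values of these 24 genes in limma lay at or below 1.88e-07.

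**Figure D2:**
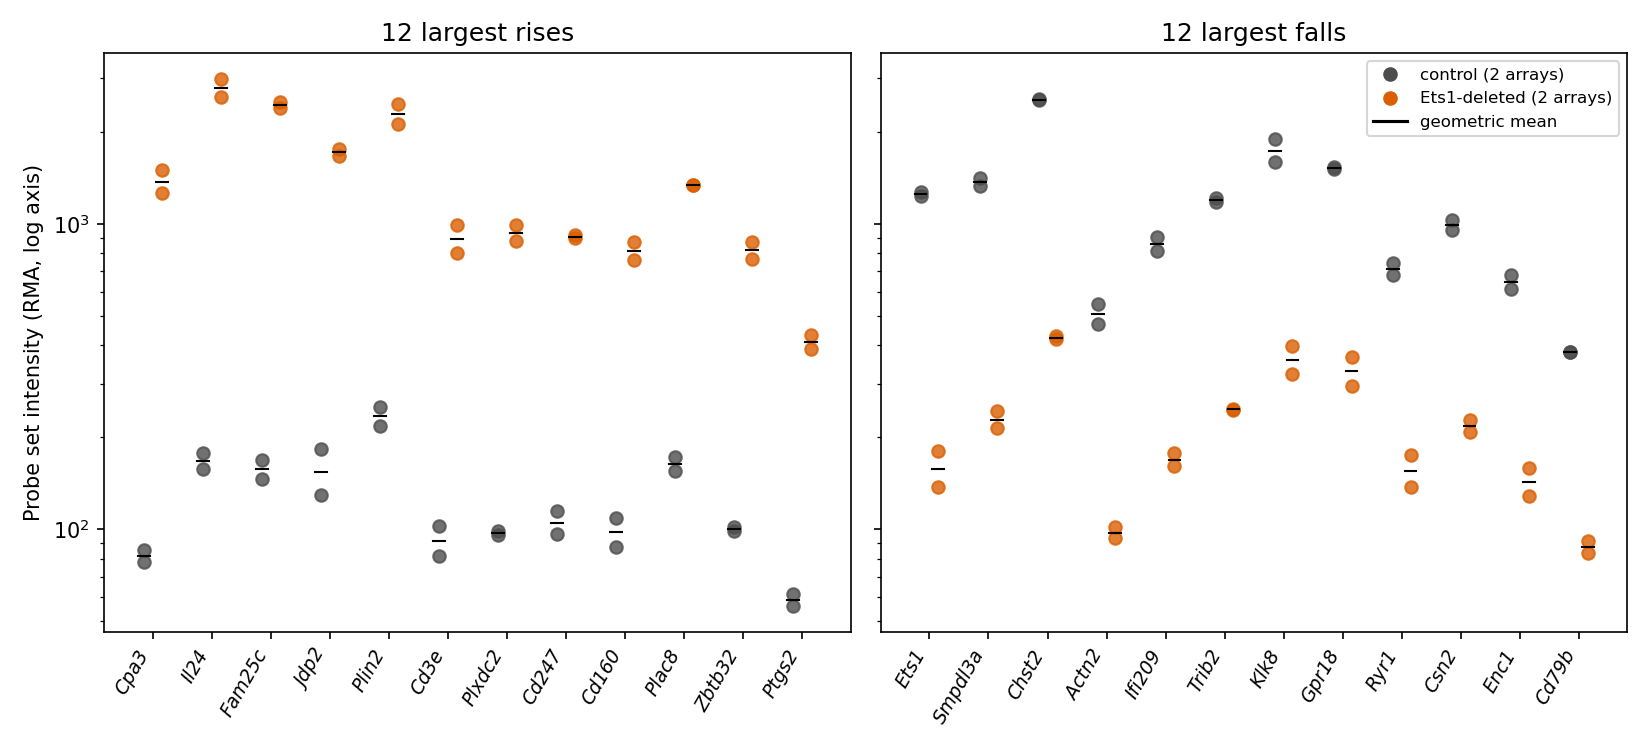
Probe set intensity (RMA values, log axis) of the 12 genes with the largest rise and the 12 with the largest fall, control arrays in grey, Ets1-deleted arrays in orange, bars at geometric means. In each gene both Ets1-deleted arrays lie on one side of both controls, and Cpa3 goes from 85.9 and 78.3 to 1497 and 1261 intensity units.

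In all, 2900 of the 10873 genes (26.7%) passed an adjusted p of 0.05 in limma, 1512 higher and 1388 lower in the Ets1-deleted arrays. Of these, 1551 differed by less than 1.5-fold. No overlap between the groups and at least a 2-fold difference were found for 504 genes, 322 higher and 182 lower. In all 2900 called genes the groups did not overlap, which the threshold itself nearly requires, so it is not separate evidence. Among all tested genes the share without overlap was 62.6%, against 33.3% by chance. With each gene's own variance alone, which has 2 residual degrees of freedom, 13 genes passed, so the count rests on variance shared across genes. An exact permutation test of 2 against 2 arrays cannot give a p under 0.333, and the sources used here name no array batch, so a batch that followed the groups would not show.

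Among 19 tested ILC2 receptors and surface markers, 8 rose and 4 fell (9 and 6 when adjusted over the list alone). Thy1 rose by 1.91 ± 0.11, the IL-18 receptor gene Il18r1 by 1.25 and Il4ra by 1.02. The bright Il4ra probe set that moved least gave 0.09. The IL-25 receptor gene Il17rb rose by 0.93 and the IL-2 receptor gene Il2ra by 0.81. Besides Klrg1, the neuropeptide receptor gene Nmur1 (-0.68) and Ptgdr2, a prostaglandin receptor gene (-0.45), fell, while Il7r differed by 0.05. The list median was 0.05 (camera, adjusted p = 0.245). Of 20 type 2 cytokines and ILC2 effectors, 10 rose and 6 fell (11 and 6 adjusted over the list alone). Csf2 rose by 2.79 ± 0.12, Pparg, a nuclear receptor of lipid metabolism, by 2.69, Il6 by 2.53, Il9 by 2.16 and Arg1 by 1.56. The opioid precursor gene Penk (-1.68), the prostaglandin D synthase gene Hpgds (-1.30), Il4 (-0.68) and Tph1, for serotonin synthesis (-0.63), fell. Relative to other genes this list was higher (median 0.42, camera adjusted p = 0.0359), with adjusted p = 0.516 with an estimated correlation. The camera adjusted p was 0.0517 with the mean over probe sets and 0.0718 with the array floor subtracted. Markers of mast cells and basophils and of myeloid cells were higher in the same arrays, with list medians of 0.46 and 0.66.

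Of 31 tested transcription factors of the ILC and T lineages, 11 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.08 (camera, adjusted p = 0.0508). With any 1 array left out this list passed, at camera adjusted p between 0.00807 and 0.0468, and without the filter at 0.0387, while all 4 arrays gave adjusted p = 0.318 with an estimated correlation. Gfi1, a repressor that ILC2 need, rose by 2.00 ± 0.12, Egr2 by 1.29, Sox4 by 1.27, Zbtb16 by 1.13 and Bach2 by 1.04. Zbtb16 marks ILC precursors but also T cells that make IL-17. It read 68.61 and 70.44 intensity units in the controls, near the floor, and 150.2 and 155 in the Ets1-deleted arrays. In the 6 E proteins and Id proteins, Tcf4 rose by 0.56 and Id3, an inhibitor of E proteins, fell by 1.31. The Tcf4 call was lost with the mean over its probe sets (0.23, adjusted p = 0.0538 with limma). In this list 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.359). Id2 differed by 0.35 and stayed short of the threshold (adjusted p = 0.0749 with limma). Among 16 other ETS family genes, 6 rose and 4 fell, also when adjusted over the list alone (camera, adjusted p = 0.433). Etv5 rose by 1.38, Erg by 0.84 and Etv3 by 0.53, and Elf1 fell by 0.74.

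The 26 genes of the cytokine (STAT5) response went both ways, 11 higher and 5 lower (12 and 5 adjusted over the list alone, camera adjusted p = 0.0508). Dusp5, a phosphatase gene that acts on ERK, rose by 1.75 ± 0.12, the survival gene Bcl2 by 1.39 and Socs2 by 1.31, and Slfn2 (-1.19) and the kinase gene Pim2 (-1.04) fell. The STAT5 list passed camera without control 1 (adjusted p = 0.0298) or Ets1-deleted 2 (0.0133), without the filter (0.0296) and with the stricter filter (0.0244), against adjusted p = 0.507 with an estimated correlation. In the NF-kB and IL-33 response, 4 of 25 rose and 7 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.394). Tnfrsf9 rose by 1.35 and Tnfaip3, a feedback inhibitor of NF-kB, by 1.12, and Irf4 (-0.75) and Gadd45b (-0.75) fell. Among 14 Notch targets, 3 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.549). Hey1, a direct Notch target, and Notch1 fell (-1.49 ± 0.11 and -0.68), while Rbpj, the DNA-binding partner of Notch, rose by 1.34.

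In the amino acid and ER stress response (ATF4), 23 of 32 genes rose and 0 fell (24 and 0 adjusted over the list alone, median 0.48). Vldlr rose by 2.36 ± 0.12, the amino acid transporter genes Slc7a3 and Slc7a11 by 1.88 and 1.78, Chac1, which degrades glutathione, by 1.88 and Trib3 by 1.48. The camera adjusted p was 6.02e-11, and adjusted p = 0.298 with an estimated correlation. Glycolysis and hypoxia genes rose in 14 of 27 cases with 0 falls (16 and 1 adjusted over the list alone, median 0.33). Egln3, an oxygen sensor gene, rose by 1.74 ± 0.11, hexokinase 2 (Hk2) by 1.30, Ndrg1 by 1.24 and Vegfa by 1.21. This list passed camera with adjusted p = 1.09e-06, and with an estimated correlation adjusted p = 0.298. Of 18 cholesterol synthesis genes, 11 rose and 0 fell, also when adjusted over the list alone, with a median of 0.44. Cyp51 rose by 0.81, Hsd17b7 by 0.73, Fdft1 by 0.67 and Hmgcs1, the entry enzyme, by 0.52. Only 2 of the 4 bright Fdft1 probe sets and 4 of the 5 of Hmgcs1 went up, and the Fdft1 call was lost with the mean over probe sets (limma, adjusted p = 0.066). Cholesterol genes gave a camera adjusted p = 0.000633, and adjusted p = 0.298 with an estimated correlation. Among 23 immediate early genes, which respond within minutes to signals, 10 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.27). Ier3 rose by 2.54 ± 0.12, Maff by 1.64 and Jun by 1.22, and Zfp36, which destabilises cytokine mRNA, fell by 0.81. Their camera adjusted p was 0.00536, with adjusted p = 0.298 with an estimated correlation. Myeloid and mast cell markers (medians 0.66 and 0.46) and Cd3e (3.28) were higher in the same arrays as these 4 lists.

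Cell cycle genes moved little: 1 of 49 rose and 5 fell (1 and 1 adjusted over the list alone), with a median of -0.02 (camera, adjusted p = 0.359). Mki67, which marks cycling cells, fell by 0.66 ± 0.11. Among 30 apoptosis and p53 genes, 3 rose and 11 fell (4 and 11 adjusted over the list alone, camera adjusted p = 0.0956). The p53 target genes Zmat3 (-1.76 ± 0.11), Phlda3 (-1.51 ± 0.11), Tnfrsf10b (-0.90), Mdm2 (-0.61) and Ccng1 (-0.53) fell. Bcl2, Pmaip1 and Bcl2l11 rose, by 1.39, 1.14 and 0.96. This list passed camera without Ets1-deleted 1 (adjusted p = 0.0468) and without the filter (0.0387), against adjusted p = 0.516 with an estimated correlation. Of 23 costimulatory and coinhibitory receptors, 10 rose and 7 fell (11 and 7 adjusted over the list alone, camera adjusted p = 0.128). Pdcd1, which encodes PD-1, rose by 2.78 ± 0.12 and Cd28 by 2.18, and Cd80 (-1.63), Ctla4 (-1.38) and Vsir (-1.11) fell. These receptors passed camera without control 1 (adjusted p = 0.00645) or control 2 (0.0119), against adjusted p = 0.507 with an estimated correlation. Among 25 genes of chemokine receptors, adhesion and migration, 8 rose and 6 fell (9 and 10 adjusted over the list alone). Ccr2 rose by 1.57, Ccr6 by 1.03 and Itgb3 by 0.94, and Itga2 (-1.02) and Itgae (-0.72) fell. The median of this list was -0.09 and its mean 0.08, and camera gave it the direction of the mean with adjusted p = 0.792. In the interferon response, 4 of 31 genes rose and 9 fell (5 and 14 adjusted over the list alone, median -0.25). The antiviral effector genes Oas3 (-0.86) and Ifit1 (-0.75) fell, and Oasl2 and Usp18 rose by 0.94 and 0.71. Myeloid and mast cell markers (medians 0.66 and 0.46) were higher in the same arrays. The interferon list had a camera adjusted p = 0.0415, and adjusted p = 0.318 with an estimated correlation. That call was lost without control 1 (adjusted p = 0.122), control 2 (adjusted p = 0.118) or Ets1-deleted 1 (adjusted p = 0.0709) in camera, and with the array floor subtracted (adjusted p = 0.0718).

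Markers of other blood cells were measured as well. Of 15 tested T cell genes, 7 rose and 2 fell, also when adjusted over the list alone (median 0.19). Besides Cd3e and Cd247, Cd3d rose by 2.58 ± 0.11 and Cd27 by 0.73, while Zap70, the kinase of the receptor complex, fell by 1.13. The T cell list gave a camera adjusted p = 0.00121, and adjusted p = 0.298 with an estimated correlation. Of 16 NK and ILC1 genes, 7 rose and 2 fell, also when adjusted over the list alone (median 0.22). Klrc1 rose by 2.09, Ccl3 by 1.58 and Xcl1 by 1.10, and the integrin gene Itga2 fell. Their camera adjusted p was 0.0151, and adjusted p = 0.507 with an estimated correlation; under the stricter filter on dim genes it was 0.431, and with the mean over probe sets 0.0517. Of 8 ILC3 genes, 6 rose and 0 fell, also when adjusted over the list alone (median 0.77). Il17a rose by 2.20 ± 0.12 and Il1r1 by 1.84. ILC3 genes gave a camera adjusted p = 0.000633, adjusted p = 0.298 with an estimated correlation and 0.0637 under the stricter filter.

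Of 20 myeloid genes, 17 rose and 1 fell, also when adjusted over the list alone (median 0.66). The granule protease gene Ctsg rose by 1.51 ± 0.12, the Fc receptor gene Fcgr3 by 1.18 and S100a9 by 1.14, and Ctss fell by 0.84. The camera adjusted p was 1.23e-08 for the myeloid list, and adjusted p = 0.307 with an estimated correlation. Of 12 mast cell and basophil genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone, median 0.46). After Cpa3, the cytokine receptor gene Csf2rb rose by 2.34 ± 0.13 and the protease gene Mcpt2 by 1.39. This list had a camera adjusted p = 0.000384, and adjusted p = 0.298 with an estimated correlation. Only 18 myeloid and 8 mast cell genes reached the dim limit in both controls, fewer than were tested. Of 7 B cell genes, 0 rose and 2 fell, also when adjusted over the list alone (camera, adjusted p = 0.183, and 0.0121 without control 1; adjusted p = 0.516 with an estimated correlation). Among 23 genes of OP9 stroma and fibroblasts, 3 rose and 2 fell, also when adjusted over the list alone. Timp3, an inhibitor of matrix proteases, rose by 2.55 and Pdgfrb fell by 0.85. The stromal median was -0.09 and the mean 0.06, and camera gave the direction of the median (adjusted p = 0.792). Of 5 erythroid and platelet genes, 1 rose, the platelet chemokine gene Pf4 (0.93), also when adjusted over the list alone, with a median of -0.02 and a mean of 0.18 (camera, adjusted p = 0.455).

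**Figure D3:**
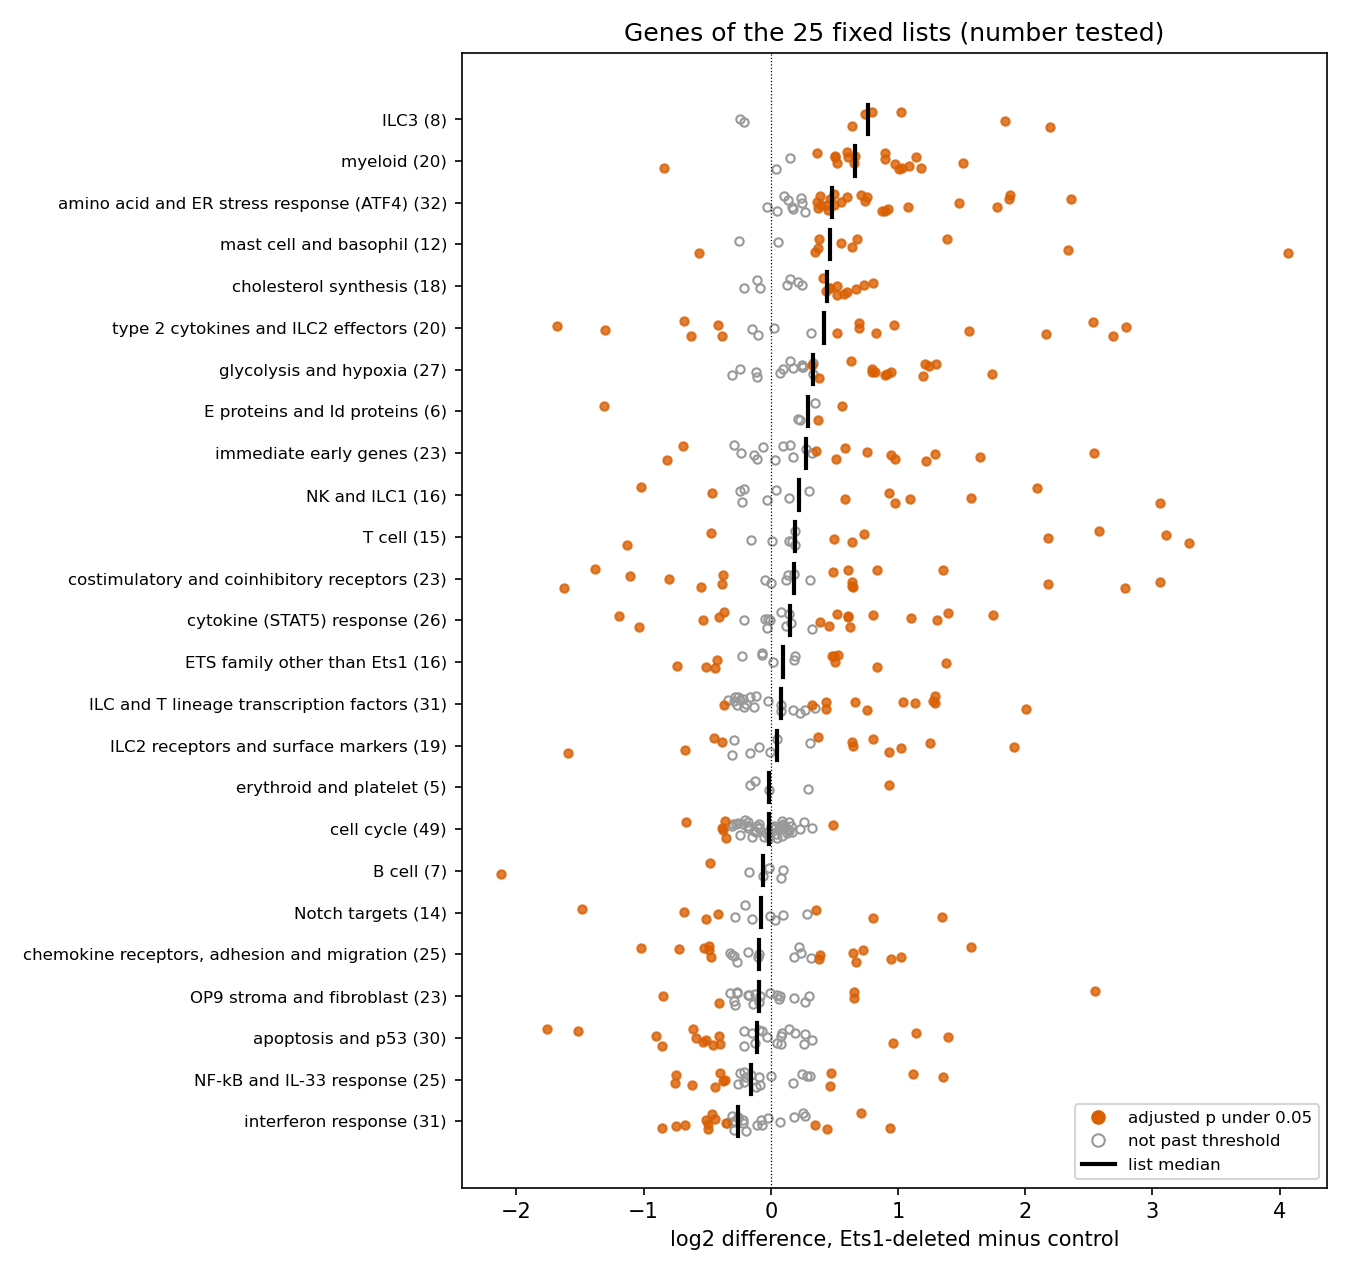
The log2 difference (Ets1-deleted minus control) of each tested gene in the 25 fixed lists, with list medians as black bars, genes past an adjusted p of 0.05 in orange and the rest as open grey circles. Medians lie highest for the ILC3 (0.77), myeloid (0.66) and ATF4 (0.48) lists and lowest for the interferon list (-0.25). Some genes of the ILC3, NK and mast cell lists lay below the dim limit in both controls, such as Nrp1, Klrc1 and Cpa3. They were tested only through higher Ets1-deleted values.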

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

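The tests for mast cells, myeloid cells, a lower share of ILC2 and both kinds of T cells were chosen after the results were seen, and the test of the genes beside Ets1 before. A signal appeared in probe sets that no comparison used. Of 2083 bright probe sets without a gene name, 47 passed an adjusted p of 0.05 in limma at 2-fold or more with no overlap. Of these, 32 were higher and 15 lower. Among 10873 tested genes, 504 were 2-fold apart with no overlap, but no p-value was asked of them. The 2 shares therefore cannot be compared. The array maker's 3' control probe set for the transferrin receptor was higher in the Ets1-deleted arrays by a log2 difference of 1.335, its middle probe set by 1.13 and its 5' probe set by 0.96.

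Myeloid and mast cell markers were higher in the Ets1-deleted arrays, with medians of 0.66 over 20 and 0.46 over 12 tested genes. Members dim in the controls were tested only if their Ets1-deleted values were higher, which can tilt these medians upward. If all other cell types made up for a lower share of ILC2, B cell, stromal and erythroid markers would rise too. All 3 medians of those lists lay more than 1 SD over the myeloid genes (0.509) below the myeloid median. The B cell and erythroid lists hold only 7 and 5 tested genes, some near the floor, such as Vpreb3 and Klf1, so they weigh little. The stromal list, with 23 tested genes, argues against such an even rise. A lower share made up by particular cell types, such as myeloid or mast cells, would not show in these lists. Mast cells or basophils stay possible: the 14 markers at or below 250 intensity units in both controls had a median of 0.456 (SD 0.679) and 8 rose, short of the 4.07 of Cpa3 but not near 0, while Fcer1g, abundant in mast and myeloid cells, differed by 0.04. Myeloid cells cannot be told apart from a change within ILC2 either. The 8 markers too dim to test had a median of 0.0948 (SD 0.133), near the floor. A marker that rose far would have been tested, so a small median among them was largely set by the filter. Also, 18 of the 28 myeloid and 8 of the 16 mast cell genes already reached the dim limit in both controls, and 3 and 0 are in another list. The sort for ICOS would remove cells without it, and an effect of the genotype within ILC2 stays open and untested.

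Cd3e, Cd3d, Cd247 and Cd28 were higher, by log2 differences of 3.28, 2.58, 3.11 and 2.18. Cells with Cd4 or Cd8 and developing T cells would bring their other genes. The 11 other T cell markers at or below 250 intensity units in both controls included Cd4, Cd8a, Cd5, Cd6, Rag1 and Ptcra. They had a median of 0.0724 (SD 0.272) and 1 rose, Cd2 by 0.64, short of the 2.18 of Cd28. These markers belong to different kinds of T cell, so their median alone could miss one kind. The small SD and the lone rise argue against such cells. Lat differed by 0.19 and Zap70 fell by 1.13, which counts against neither these cells nor T cells that make IL-17. Both genes read above 250 intensity units in at least 1 control, so added T cells need not raise them. T cells that make IL-17 without Cd4 or Cd8 remain a candidate explanation, since genes chosen after their values were seen rose with the CD3 genes. These were Cd163l1 by 2.71, 5830411N06Rik by 2.52 and Sox13 by 1.32, besides Il17a and Il1r1. The receptor segment Trbv13-2, whose probes related segments could share, rose by 2.39. Cd3g rose by only 0.50, but it too read above 250 intensity units in at least 1 control. The 6 dim markers of such cells not looked at before had a median of 0.219 (SD 0.983; 3 rose, Ramp1 by 2.14), against 1.13 for all 15, while Blk (0.08) and Maf (-0.26) did not pass and of the brighter ones Serpinb1a rose by 1.11 and Aqp3 fell by 1.39, so these cells cannot be told apart from a change within ILC2. Of the 21 T cell genes with a probe set, 12 reached the dim limit in both controls and 3 are in another list, T cells can carry ICOS and pass that sort, and an effect of the genotype within ILC2 is untested.

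Genes beside Ets1 may be carried along with the deleted allele where mice differ in background. Of the 20 nearest tested genes, 8 (40%) passed the threshold against 26.6% of the others (one-sided Fisher's exact p = 0.137), Aplp2 higher and 7 lower (Nfrkb, Snx19, Tirap, Foxred1, Fam118b, Cdon and Ddx25). With 1 array left out 6 or 7 passed, Snx19 losing its call each time, Nfrkb without control 2, and Ddx25 without control 2 or Ets1-deleted 1, where St3gal4 and Rpusd4 respectively gained one; Fisher's exact p then lay between 0.109 and 0.219, and was 0.00835 without the filter, where the others include dim genes. The bound set beforehand, a p of 0.05 or above, was too lax to exclude such an effect, because the exact 95% interval of the share runs from 19.1% to 63.9% and so holds the share of the other genes and much larger ones. A carried segment and an effect of Ets1 on its neighbours cannot be told apart with these arrays.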

How the results depend on the processing

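The floor subtraction was chosen after seeing the data, and the other alternatives before. Called genes numbered 2238 to 2736 with 1 array left out, 2949 after repeated quantile normalization, 2916 after median centring, 2888 without the filter, 2121 with the stricter filter (of 7493 genes), 3055 with the mean over probe sets, 2900 with a variance trend, 2925 with robust variances and 2465 with the floor subtracted. Ordinary variances left 13 calls, 7 higher and 6 lower, 10 of them among the 2900. They have 2 residual degrees of freedom and no shared variance. With 1 row per probe set there were 5480 calls, of probe sets and not of genes. At a threshold of 0.1 there were 3669. The 504 genes 2-fold apart became 1350 at 1.5-fold and 884 with the floor subtracted, which widens folds of dim genes by construction. Same-numbered arrays share only a number (correlation of their deviations 0.167). With the replicate block 3252 genes passed, and 0 of the followed genes and lists lost their call.

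Of 317 called genes that were followed, 314 lost their call with ordinary variances. Under the other alternatives, 184 of the 249 genes tested in all of them kept it, and so did 44 of the 68 left untested in some, wherever they were tested. One turned: Ccnd3 went from 0.39 to -0.1035 with the mean over probe sets (limma, adjusted p = 0.378), as only 1 of its 3 bright probe sets rose. Lists past the threshold numbered 9 to 14, but 0 with the estimated correlation. With the floor subtracted the type 2 cytokine and interferon lists each had a camera adjusted p of 0.0718. Camera was not run with robust variances, which it does not take. The other 2 splits of the arrays gave 0 genes each past an adjusted p of 0.05 in limma (74 and 4 at an unadjusted p under 0.05). Each of them joins a control with an Ets1-deleted array, so the group difference enters the variance and few calls were fixed in advance. Also, 3 splits are too few for a share under 0.05. Signal over background limits genes near the floor.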

Other observations

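The 3 gene lists tested here were drawn up after the fixed lists had been seen, from genes that no fixed list holds, and each test was set before the values of those genes were seen. Dusp5, Dusp6 and Etv5, which are switched on by the ERK pathway, had risen by 1.75, 1.10 and 1.38. One hypothesis was that ERK feedback genes were higher as a group. Of 11 further ones, 8 rose and 0 fell, with a median of 0.864 (camera p = 1.86e-06, and p = 0.101 with an estimated correlation). Errfi1, an inhibitor of the EGF receptor, rose by 2.10, Emp1 by 1.95, the phosphatase gene Dusp4 by 1.65 and Spry2, a feedback inhibitor of the pathway, by 1.21. Spry4, the smallest of the rises (0.32), lost its call with each array left out. This is consistent with higher ERK output in the Ets1-deleted samples, which transcript levels alone do not measure. Myeloid, mast cell and CD3 genes were higher in the same arrays, so cells other than ILC2 stay open as a source for the rises.

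Pparg and Plin2 had risen by 2.69 and 3.28, and a second hypothesis was that lipid storage genes and PPAR targets were higher as a group. Of 20 further genes, 8 rose and 3 fell, with a median of 0.246 (camera p = 0.0116, and p = 0.11 with an estimated correlation). Hilpda, which acts on lipid droplets, rose by 1.57, the cholesterol exporter gene Abca1 by 1.27, Dgat1, which makes triglycerides, by 0.92 and the desaturase gene Scd1 by 0.84. Abcg1, another sterol exporter gene, fell by 0.78. Angptl4 (0.06), Lpl (0.04), Pnpla2 (0.01), Plin3 (0.09) and Cpt1a (0.25) did not pass the threshold. Without the filter the falls of Lipa and Mgll lost their call (limma, adjusted p = 0.109 and 0.0562), as did Fabp4 with the mean over probe sets (0.24, adjusted p = 0.0573). Lipa also lost it without control 1 (-0.38) or Ets1-deleted 1 (-0.20), and Mgll without control 2 (-0.36) or Ets1-deleted 2 (-0.34). The rise of Acadvl lost its call without control 1 (0.33), without Ets1-deleted 2 (0.35) or with the floor subtracted (0.43). Myeloid and mast cell markers (medians 0.66 and 0.46) were higher in the same arrays. Members went both ways, so any common programme may cover part of the list.

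The p53 targets Zmat3, Phlda3 and Mdm2 had fallen, and the last hypothesis was that p53 targets were lower as a group. Of 20 further targets, 9 fell and 3 rose, with a median of -0.283 (camera p = 0.0145, and p = 0.203 with an estimated correlation). Ei24 (-1.10), Dcxr (-0.80) and Ckap2 (-0.75) fell, while Perp rose by 2.27 and the thiamine transporter gene Slc19a2 by 1.06. Of the smaller falls, Psrc1, Ercc5, Gtse1 and Tap1 lost their call without control 2, Polk, Ercc5 and Tap1 without control 1, Ercc5 and Tap1 without Ets1-deleted 1, and Polk without Ets1-deleted 2. Polk and Tap1 also lost it with the mean over probe sets, and the rise of Dusp14 lost its call without control 2. Tap1 also lost its call with the floor subtracted. A lower p53 output is possible, but the test rests on modest falls and has clear exceptions. Among the targets that did not pass the threshold were Sesn1 (-0.13), Aen (-0.17), Rps27l (-0.18), Xpc (-0.16) and Ddb2 (0.08). The ERK and lipid lists passed 0.05 in the directional test of fry, and the p53 list did not. Myeloid, mast cell and CD3 genes were higher in the same arrays, so a different mix of cells stays open as a source of the falls.

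The female-specific transcript Xist read 1031 to 1612 intensity units and the Y-linked Kdm5d, Eif2s3y and Uty 55.5 to 78.1 on all 4 arrays. The 3' over 5' log2 ratio of the Gapdh control probe sets was 0.755 and 0.716 in the controls and 0.679 and 0.586 in the Ets1-deleted arrays. For actin it was -0.06 and -0.27 against -0.06 and -0.02, and for the transferrin receptor, whose probe sets were all higher in the Ets1-deleted arrays, -0.95 and -0.99 against -0.39 and -0.80.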
